A study of Mus musculus with 24 samples.

How the data were processed

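RNA libraries from mouse CD4+ T cells in Th1 culture were analysed, 4 for each of 6 groups made by genotype (WT or Rasa3 KO) and day of culture (1, 2 or 4). Per the labels' protocols, total RNA was extracted, messenger RNA was selected on poly-T beads and fragmented, and complementary DNA was made from random primers. The authors deposited a table of raw counts of reads per gene, with 1 column per library, gene identifiers, symbols, coordinates, biotypes and lengths. The genome build was GRCm38 per the submitters' processing notes. The aligner, the counting tool, its use of strand and the annotation release are not given in the sources used here. Reads shared between near-identical or overlapping genes can therefore have been split or dropped in a way that cannot be traced. Each library was put in its group from its genotype label and title, and replicate numbers were those of the titles.

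Counts were used as deposited. Totals ran from 12652594 to 19518812 per library, and the lowest share of a library's counts held by the tested genes was 99.9%. All 54532 entries had a symbol, and 100 symbols stood on more than 1 entry, which were kept apart by identifier. Genes were kept by edgeR's filterByExpr by group (minimum count 10, minimum total 15), which left 15086, of which 12283 were protein-coding. R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0 were used. Library sizes were scaled by TMM. One model with a mean for each of the 6 groups was fitted to all 24 libraries (18 residual degrees of freedom) with estimateDisp, glmQLFit with robust estimation and glmQLFTest, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The comparisons were KO against WT at each day, the 3 differences of the KO effect between days, and WT day 2 against day 1 and day 4 against day 2. Printed CPM are counts over TMM-scaled library sizes, with the sample SD, and a prior count of 2 was used for log2 CPM. For genes without reads in a group, a lower bound of the fold was taken against 3 counts over the group, and with 1 to 3 counts a ratio with its 95% exact interval. Such bounds and intervals cover counting error only.

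The comparisons, tests, alternatives, gene lists and the rule for named genes were fixed before the data were examined, and later additions are named as such. The rule named Rasa3, Hck, Tbx21, Ifng, Stat4, Il12rb2, Cxcr3 and Stat1 in every comparison. Between genotypes it added the 8 higher and 8 lower genes with the largest log2 change among those with an adjusted p under 0.05, a mean of at least 1 CPM in either group, no overlap between groups and a symbol that is not a Gm number, a Rik name or an antigen receptor segment, and the 3 called members of each list with the smallest p. For WT days it added the 6 higher and 6 lower by the same criteria, and for differences between days the 5 called genes with the smallest p. The list members named for WT days were among the called members with the smallest p, chosen after the values were seen.

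Of 29 gene lists, 22 held programmes: Th1 program, cytotoxic effector, Th2 program, Th17 program, Treg signature, Tfh signature, naive and quiescence, type I interferon response, interferon gamma response, T cell receptor (TCR) and Ras-ERK target genes, T cell cytokines, integrins and Rap1 adhesion, Ras and Rap regulators, Src family kinases and regulators, inhibitory receptors, glycolysis, oxidative phosphorylation, cholesterol synthesis, ATF4 and amino acid stress, p53 and apoptosis, S phase, and G2 and mitosis. The other 7 held markers of other cells: myeloid, dendritic, B, CD8 T, NK and innate-like T, erythroid and platelet, and stromal and endothelial. The 28 lists with at least 3 tested members were tested between KO and WT by limma's camera on voom values with a preset correlation of 0.01, and with an estimated correlation and limma's fry as alternatives. Scores are the mean log2 CPM of members. Single values were compared by exact two-sided permutation tests over the 35 splits of 8 libraries.

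The model was tested on simulated data for the same 15086 genes, with 67 genes changed 1.5-fold, 67 changed 2-fold and 66 changed 4-fold in each comparison. With one spread for all days it found 32.8%, 83.6% and 97.0% of them at day 1, 41.8%, 70.1% and 97.0% at day 2 and 28.4%, 74.6% and 95.5% at day 4, with 9, 11 and 9 false calls. When each day had its own spread, as in the real libraries, the shares found at day 1 were 34.3%, 83.6% and 95.5%, but 137 of 279 calls were false, against 6 of 135 at day 2 and 2 of 134 at day 4. A list of 25 genes changed 1.2-fold was called in all 3 comparisons, and of 28 unchanged lists 0 or 1 was. Simulated genes varied independently, so this does not test lists whose members vary together. In the real libraries, splits other than KO against WT called a median of 2.5, 4 and 5 lists at days 1, 2 and 4.

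The alternatives fixed beforehand were DESeq2's size factors and upper-quartile factors in edgeR, no filter beyond 1 read, a mean of at least 1 CPM, protein-coding genes alone, DESeq2's Wald test, limma-voom, the libraries of the compared groups alone, the replicate number as a block, a threshold of 0.01, a log2 change of at least 1, camera on ranks, and each library left out in turn. Alternatives added after seeing the data were the omission of 3 day 1 libraries (WT replicates 1 and 3, KO replicate 3), limma-voom with sample quality weights, replicate numbers 1 and 2 against 3 and 4 as a block, days 2 and 4 alone, and the mean KO effect over days. Whether replicate numbers paired the libraries was checked by correlating deviations from group means. Same-numbered KO and WT libraries correlated by -0.0803 to 0.207 at day 1, 0.0552 to 0.193 at day 2 and 0.127 to 0.338 at day 4. A correlation over 0.1 in every pair was taken to show pairing. By this cut pairing was shown at day 4 alone, from the data and not from the labels. At days 1 and 2 it was not shown and stays possible, since same-numbered libraries were of the same sex on all days. Counts in other regroupings of the libraries were obtained from all 35 splits of 8 libraries, or from 100 drawn at random.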

Results

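Gene expression was measured by sequencing polyadenylated RNA from mouse CD4+ T cells. The cells were taken as naive cells from spleen and lymph nodes and grown in culture that polarises them to T helper 1 (Th1) cells, the helper subset that makes interferon gamma. They came from wild-type (WT) mice and from mice with a knockout (KO) of Rasa3, which encodes a GTPase-activating protein for the small GTPases Ras and Rap1. RNA was collected after 1, 2 and 4 days, which gave 6 groups of 4 libraries and 24 libraries in all. By its title, the series asked whether RASA3 restrains Th1 differentiation and whether the kinase HCK is involved. The labels do not say whether replicates were separate animals or cultures. Xist and Y-linked transcripts show that each group held libraries from both sexes, and so from more than 1 animal. How many animals there were stays unknown, so p-values measure the spread between these libraries, part of which may be technical. Total counts per library ranged from 12652594 (KO day 1, replicate 3) to 19518812 (WT day 1, replicate 1), with a median of 15858692.5. Of 54532 genes in the table, 29447 had at least 1 read and 15086 were tested. Expression is given as CPM, the counts scaled to library size with trimmed-mean (TMM) factors, as mean ± SD with n = 4 per group unless stated. No pair of replicates agreed within sampling noise, and the lowest chi-square per degree of freedom was 4.53.

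The libraries separated by day of culture. The first principal component held 68.4% of the variance and set the 8 libraries of day 4 apart from those of days 1 and 2, and the second held 10.8%. A few libraries lay away from their groups. In WT day 1 replicates 1 and 3, ribosomal protein genes took 10.9% and 8.96% of counts, against 6.10% and 6.15% in replicates 2 and 4. The same 2 libraries had higher Igkc, an immunoglobulin transcript of B-lineage cells (151 and 97.7 CPM, against 35.8 and 25.3), and lower Cd4 (197 and 277 CPM, against 391 and 447). The T cell receptor gene Trbc1 was higher in them (563 and 425 CPM, against 268 and 293), as was Trbc2 (836 and 702 CPM, against 435 and 506). Their counts lay on shorter genes, with a typical annotated gene length of 3511 and 3781 bases, against 4382 and 4337. This length is the mean over genes weighted by counts on the log scale. It shifts with which genes take the counts and does not measure the length of the RNA. In KO day 1 replicate 3, mitochondrial transcripts took 3.22% of counts, against 1.31% to 1.5% in the other KO day 1 libraries.

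**Figure D1:**
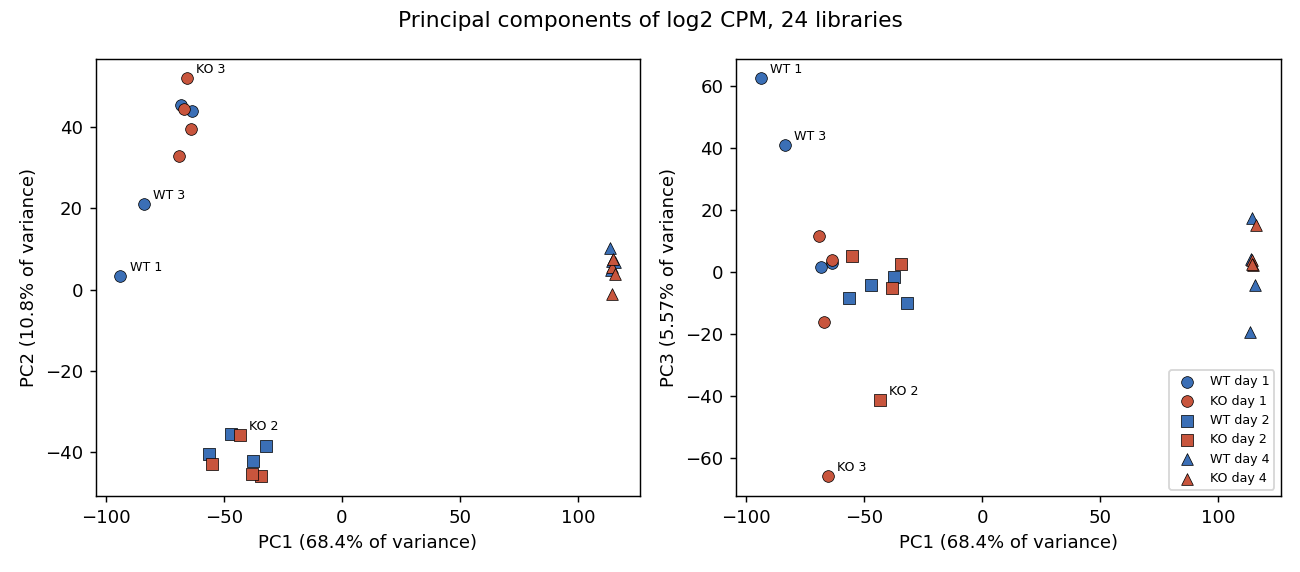
Principal components of log2 CPM over the 24 libraries, with component 1 (68.4% of variance) against component 2 (10.8%) at left and component 3 (5.57%) at right. Each point is a library, colour gives the genotype and shape the day, and labels mark day 1 and day 2 libraries away from their groups. Libraries fall by day, and WT and KO libraries of a day lie together apart from the labelled ones.

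Rasa3 (ENSMUSG00000031453, chromosome 8, 13566948 to 13677603, GRCm38) was lower in every KO library than in every WT library of the same day. At day 1 the KO libraries held 9.36, 13.3, 12.2 and 12.5 CPM and the WT libraries 17.6, 27.0, 20.4 and 27.8. At day 2 the KO libraries held 4.58, 4.76, 4.68 and 5.12 CPM and the WT libraries 15.2, 14.2, 13.2 and 10.3. At day 4 the KO libraries held 26.1, 27.5, 23.1 and 19.1 CPM and the WT libraries 39.9, 46.4, 41.9 and 38.8. Rasa3 mRNA was thus lowered and still present in KO cells, at 4.78 ± 0.235 CPM against 13.2 ± 2.10 at day 2, or 36.2% of WT by the fitted value. Each day's separation had an exact two-sided permutation p of 0.0286, the smallest that 4 against 4 libraries can give, and 0.137 after adjustment over 24 such tests. Counts per gene do not show which exons the remaining reads cover.

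**Figure D2:**
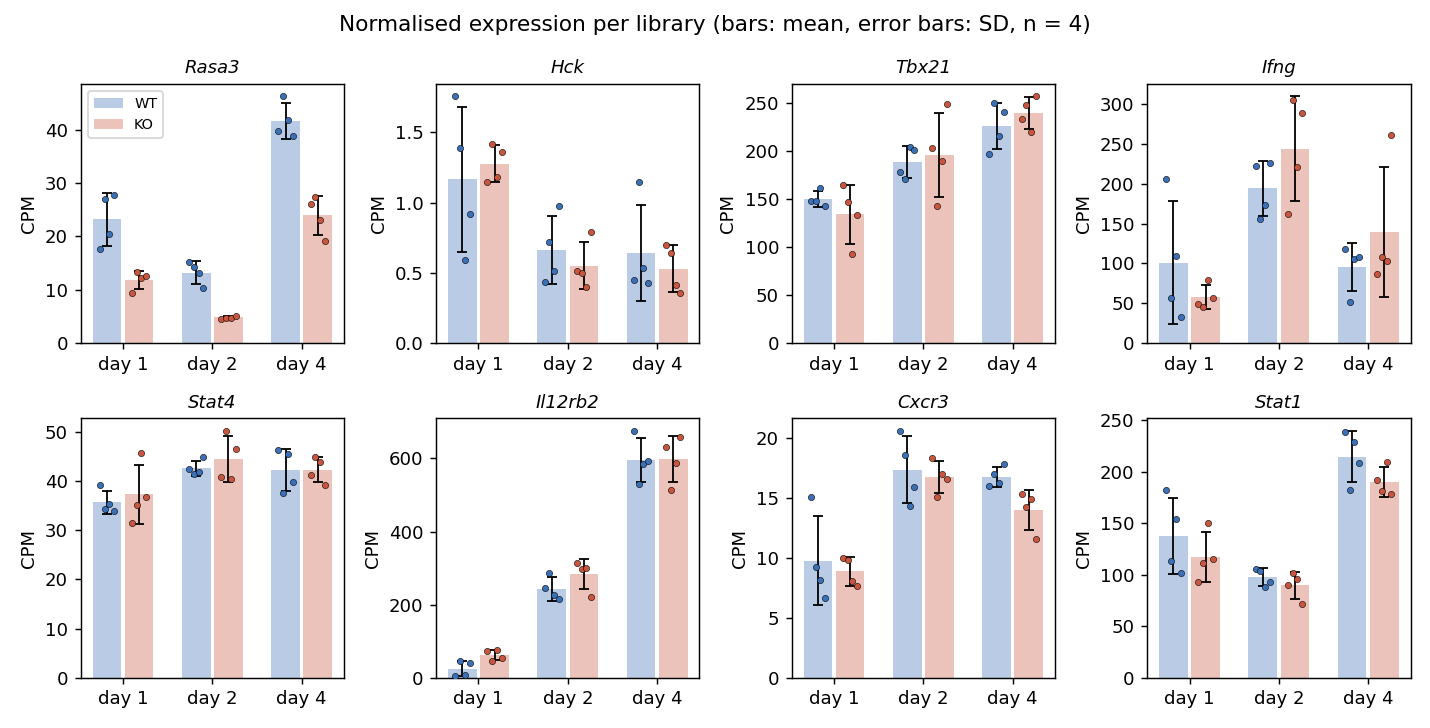
CPM of Rasa3, Hck and 6 Th1 genes in each library (vertical axes start at 0) by day of culture, with points for libraries, bars for the mean and error bars for the SD of 4 libraries. Rasa3 is the gene whose KO points lie below all WT points on all 3 days, and Il12rb2 rises with time in both genotypes.

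At day 1, the first comparison of KO with WT, Rasa3 fell by 0.97 on the log2 scale (SE 0.156, adjusted p = 0.0309 by edgeR's quasi-likelihood test) and was the only gene of 15086 to pass. Il12rb2, the interleukin 12 receptor chain that Th1 cells induce, stood at 61.7 ± 14.3 CPM in KO and 24.7 ± 20.6 in WT (log2 difference 1.32, SE 0.375, adjusted p = 0.0904). The low WT values came from replicates 1 and 3, at 5.38 and 8.65 CPM, against 44.4 and 40.5 in replicates 2 and 4. The KO libraries lay above all WT libraries, the lowest narrowly at 45.6 CPM (exact permutation p = 0.0286, 0.137 after adjustment over 24 tests). Il12rb2 passed with DESeq2 (adjusted p = 0.0334) and without WT replicate 2 (0.0151), WT replicate 4 (0.0205) or KO replicate 1 (0.0498), but its log2 difference was 0.98 without WT replicate 1 (adjusted p = 0.45) and 0.42 without WT replicates 1 and 3 and KO replicate 3 (adjusted p = 1). Ifng, which encodes interferon gamma, stood at 57.7 ± 15.2 CPM in KO and 101 ± 77.1 in WT (log2 difference -0.81, adjusted p = 0.19). Its WT values were 206 and 109 CPM in replicates 1 and 3 and 55.9 and 32.5 in replicates 2 and 4. The Ifng difference was -0.19 without WT replicate 1, -1.10 without WT replicate 4 (adjusted p = 0.0446) and 0.19 without WT replicates 1 and 3 and KO replicate 3. Tbx21, the gene of the Th1 transcription factor T-bet, stood at 134 ± 30.5 CPM in KO and 150 ± 7.86 in WT (adjusted p = 0.49). Hck was near the detection limit, at 1.28 ± 0.134 CPM in KO and 1.16 ± 0.514 in WT, with a 95% interval for the log2 difference of -0.60 to 0.86. Stat4, Cxcr3 and Stat1 differed by 0.06, -0.14 and -0.23 on the log2 scale, and none of them passed.

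The count of genes at day 1 depended on the tool and on single libraries. At an unadjusted p under 0.05 there were 4210 genes, where chance gives 754 if all days spread alike. The fit shared its spread over the days. Simulated day 1 libraries with that day's own spread gave 137 false calls of 279 at an adjusted p under 0.05. Genes at an unadjusted p under 0.05 were not counted there, and no simulated library stood apart from its group. The simulation therefore does not give the number to set against 4210, and the excess over 754 is not shown to be an effect of genotype. DESeq2 called 1606 genes (657 higher, 949 lower) and limma-voom called 0. Without WT replicates 1 and 3 and KO replicate 3, edgeR and DESeq2 each called 1 gene. With a single library left out, the count was 2975 without WT replicate 2, 2546 without WT replicate 4, 1775 without KO replicate 1, and 0 without KO replicate 2, 3 or 4, where Rasa3 had an adjusted p of 0.0684, 0.103 and 0.0679 at log2 differences of -1.03 to -0.98, against -0.97 with all libraries.

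Among 28 gene lists fixed before the data were examined, 2 differed at day 1 by limma's camera test with a preset correlation. The oxidative phosphorylation list, subunits of the respiratory chain and ATP synthase, was lower in KO in 32 of 33 members, with a median log2 difference of -0.60 (adjusted p = 1.19e-11). The G2 and mitosis list was higher in KO in 16 of 20 members, with a median log2 difference of 0.41 (adjusted p = 1.73e-05). With an estimated correlation neither held (adjusted p = 0.962 with an estimated correlation for oxidative phosphorylation and 0.482 for G2 and mitosis), and by limma's fry only G2 and mitosis passed (adjusted p = 0.00353). No member passed over all genes, whereas 25 oxidative phosphorylation genes fell and 12 mitotic genes rose when adjusted over the list alone. The members with the smallest p, chosen after the values were seen, included the proliferation marker Mki67 (919 ± 213 CPM in KO, 514 ± 195 in WT) and the kinetochore motor gene Cenpe (111 ± 30.1 and 64.6 ± 15.2). Of the respiratory chain genes, Ndufa6 stood at 35.8 ± 5.69 CPM in KO and 60.5 ± 22.8 in WT, and Cox7b at 73.5 ± 10.5 and 112 ± 43.7.

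The oxidative phosphorylation list moved with the libraries that stood apart. Its mean log2 CPM was 7.65 and 7.29 in WT replicates 1 and 3, against 6.75 and 6.78 in replicates 2 and 4, and 6.16 in KO replicate 3. Without those 3 libraries the list no longer differed (adjusted p = 0.97). Its camera direction turned, but only 14 of 33 members were higher in KO and the median log2 difference was -0.02. The G2 and mitosis list had scores of 6.88 to 7.14 in KO and 6.53 to 6.70 in WT, the only list of 28 whose groups did not overlap at day 1, where chance gives 2.86% of lists. Without the 3 libraries, WT replicates 2 and 4 stood against KO replicates 1, 2 and 4. In that fit all 20 G2 and mitosis members were higher in KO (median log2 difference 0.25, adjusted p = 1.49e-21 by camera with the preset correlation). By the same test a further 6 lists passed as higher in KO. These were the type I interferon response (27 of 30 members, adjusted p = 2.83e-06), the Th17 program (12 of 14, 8.5e-05), the Th1 program (22 of 26, 0.000283), erythroid and platelet markers (5 of 5, 0.000646), the Th2 program (11 of 16, 0.00266) and T cell cytokines (17 of 25, 0.00327). The preset correlation takes members to vary almost independently. For this later choice of libraries the lists were not tested with an estimated correlation, by fry or over other splits, so chance is not excluded. With all libraries 0 lists held at day 1 with an estimated correlation.

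Other lists held single members that moved at day 1 when adjusted over the list alone. Among all tested genes 27.9% had an unadjusted p under 0.05 at day 1 (edgeR), so such members do not by themselves set a list apart. Of 26 Th1 program genes, 4 rose (Il18r1, Il12rb2, Ccr5 and Bhlhe40), with Il18r1, an interleukin 18 receptor chain, at 28.5 ± 8.80 CPM in KO and 16.7 ± 3.84 in WT. The Il12rb2 difference rested in large part on WT replicates 1 and 3, at 5.38 and 8.65 CPM against 44.4 and 40.5 in replicates 2 and 4. Whether the other members named here also rest on the libraries that stood apart was not examined. Of 30 targets of T cell receptor and Ras-ERK signalling, 2 rose (Nr4a3 and Nr4a2) and 3 fell (Dusp2, Ier2 and Spry1), with Nr4a3 at 225 ± 53.8 and 143 ± 25.4 CPM. Of 25 T cell cytokine genes, 2 rose (Cd40lg and Tnfsf8) and 2 fell (Ltb and Il16). Zeb2 of the cytotoxic effector list, the Ras activator Sos1 and the B cell marker Cr2 each rose in the same sense. None of these genes passed over all genes, with adjusted p of 0.0904 or more, and none of the lists passed camera (adjusted p = 0.766 for the Th1 program, 0.989 for T cell receptor targets and 0.801 for cytokines). With all libraries the lists of other cell types did not pass either, with adjusted p of 0.363 for dendritic cell, 0.629 for erythroid and platelet, 0.801 for B cell, 0.808 for stromal and endothelial and 0.989 for myeloid and for NK cell markers. Without the 3 libraries that stood apart, erythroid and platelet markers passed as higher in KO (median log2 difference 0.67, adjusted p = 0.000646 by camera with the preset correlation alone).

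At day 2, Rasa3 fell by 1.47 on the log2 scale in KO (SE 0.166, adjusted p = 7.37e-05, edgeR). Gm2762, a long intergenic RNA gene (ENSMUSG00000107008, chromosome 13, 53393657 to 53455630), fell by 1.62 (SE 0.282, adjusted p = 0.0259), from 1.71 ± 0.145 CPM in WT to 0.548 ± 0.172 in KO. Gm2762 was named after its values were seen. The Th1 genes named in advance did not pass at day 2: Ifng stood at 245 ± 66.1 CPM in KO and 195 ± 34.9 in WT, Tbx21 at 196 ± 43.6 and 189 ± 16.5, and Il12rb2 at 283 ± 41.6 and 243 ± 32.1. Their 95% intervals for the log2 difference ran from -0.50 to 1.16, from -0.26 to 0.37 and from -0.55 to 0.99. The intervals were -0.18 to 0.30 for Stat4, -0.43 to 0.33 for Cxcr3, -0.46 to 0.22 for Stat1 and -1.11 to 0.61 for Hck. The 2 called genes stood against 243 genes at an unadjusted p under 0.05, where chance gives 754 if all days spread alike. Gm2762 lost its call with limma-voom (adjusted p = 0.696) and with the replicate number as a block (adjusted p = 0.0572, edgeR). The call was also lost when any 1 of 6 libraries was left out, with adjusted p of up to 0.312 without KO replicate 3. Its log2 difference stayed at -1.62 with limma-voom, at -1.63 with the block and between -1.66 and -1.50 in those 6 fits.

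By camera with the preset correlation, 7 of 28 lists differed at day 2. Some of the lists share genes, so the 7 are not independent results. The Th1 program and T cell cytokines both hold Ifng, Tnf and Lta, among others. The Th1 program was higher in KO in 20 of 26 members (median log2 difference 0.12, adjusted p = 0.00333), the cytotoxic effector list in 10 of 18 (adjusted p = 0.0165), T cell cytokines in 19 of 25 (adjusted p = 0.0165) and the Th17 program in 11 of 14 (adjusted p = 0.0165). Th17 scores overlapped, at 3.76 to 4.16 in KO and 3.24 to 4.20 in WT (exact permutation p = 0.429, 0.907 after adjustment over the lists). Its lowest scores were those of WT numbers 3 and 4, the female ones. Type I interferon response genes were lower in KO in 27 of 30 members (median -0.16, adjusted p = 0.000394), interferon gamma response genes in 25 of 32 (adjusted p = 0.0355) and dendritic cell markers in 8 of 9 (adjusted p = 0.0209). None held with an estimated correlation: the adjusted p was 0.0766 with an estimated correlation for the Th1 program, 0.402 for the cytotoxic, cytokine and both interferon lists, 0.455 for Th17 and 0.464 for dendritic cell markers. No member passed, over all genes or adjusted over the list alone (0 rose and 0 fell in each list). Members among the 3 with the smallest p of their lists, chosen after the values were seen, were the granule protease gene Gzmb (437 ± 82.0 CPM in KO, 333 ± 79.0 in WT), the perforin gene Prf1 (10.6 ± 0.582 and 8.40 ± 1.61), Il17f (17.6 ± 2.78 and 10.3 ± 4.10) and the interferon-induced gene Ifit2 (21.2 ± 2.98 and 24.5 ± 0.890). Of the dendritic cell markers, Itgax was at 0.0167 ± 0.0334 CPM in KO and 0.145 ± 0.170 in WT, close to the detection limit. By fry 0 lists passed, and the lowest adjusted p of the other lists by camera was 0.102. Without KO replicate 4, 0 lists passed, without KO replicate 3, 10 passed, and without KO replicate 2, the day 2 library with the most mitochondrial counts (1.95%), 4 passed.

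At day 4, no gene differed between KO and WT by edgeR (0 of 15086), while DESeq2 called 1 gene, Rasa3, and limma-voom 0. By edgeR 150 genes had an unadjusted p under 0.05, where chance gives 754 if all days spread alike. Rasa3 stood at 23.9 ± 3.75 CPM in KO and 41.7 ± 3.37 in WT (log2 difference -0.80, SE 0.152, adjusted p = 0.303 by edgeR and 0.00305 by DESeq2). Il12rb2 stood at 599 ± 62.6 CPM in KO and 596 ± 60.1 in WT, Tbx21 at 239 ± 16.8 and 225 ± 24.2, and Stat4 at 42.3 ± 2.61 and 42.3 ± 4.24. Ifng stood at 140 ± 81.5 CPM in KO and 95.6 ± 30.2 in WT, with KO replicate 4 at 261 CPM, and its 95% interval for the log2 difference was -0.29 to 1.38. Hck stood at 0.527 ± 0.168 and 0.642 ± 0.343 CPM. Cxcr3 and Stat1 differed by -0.26 and -0.17 on the log2 scale, and neither passed, though Cxcr3 was lower in every KO library than in every WT library (at most 15.3 CPM in KO, exact permutation p = 0.0286, 0.137 after adjustment over 24 tests).

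By camera with the preset correlation, 4 of 28 lists differed at day 4. Naive and quiescence genes, which mark resting T cells, were lower in KO in 17 of 20 members (median log2 difference -0.08, adjusted p = 0.00157), and this was the only list to hold (adjusted p = 0.0254 with an estimated correlation). The ATF4 and amino acid stress list was higher in KO in 23 of 23 members (median 0.15, adjusted p = 2.16e-05, and adjusted p = 0.448 with an estimated correlation). The oxidative phosphorylation list was higher in KO in 29 of 33 (median 0.09, adjusted p = 0.0115, and adjusted p = 0.87 with an estimated correlation). Type I interferon response genes were lower in 21 of 30 (median -0.14, adjusted p = 0.00157, and adjusted p = 0.657 with an estimated correlation). No member passed over all genes or adjusted over the list alone. Members among the 3 with the smallest p of their lists, chosen after the values were seen, were the transcription factor genes Klf2 (16.5 ± 4.50 CPM in KO, 22.0 ± 5.77 in WT) and Tcf7 (173 ± 29.2 and 198 ± 17.6), and the amino acid enzyme genes Gpt2 (18.3 ± 1.75 and 15.7 ± 2.14) and Psat1 (126 ± 8.76 and 114 ± 4.15). With the replicate number as a block, which pairs the day 4 libraries, B cell markers passed as well (higher in KO, adjusted p = 0.0472, against 0.161 without the block). By fry 0 lists passed, and 8 passed by camera without WT replicate 1 or 2. The naive list lost its call without KO replicate 4 (adjusted p = 0.0705), and the oxidative phosphorylation list without WT replicate 1 (adjusted p = 0.3), the day 4 library with the most mitochondrial counts (1.95%).

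**Figure D3:**
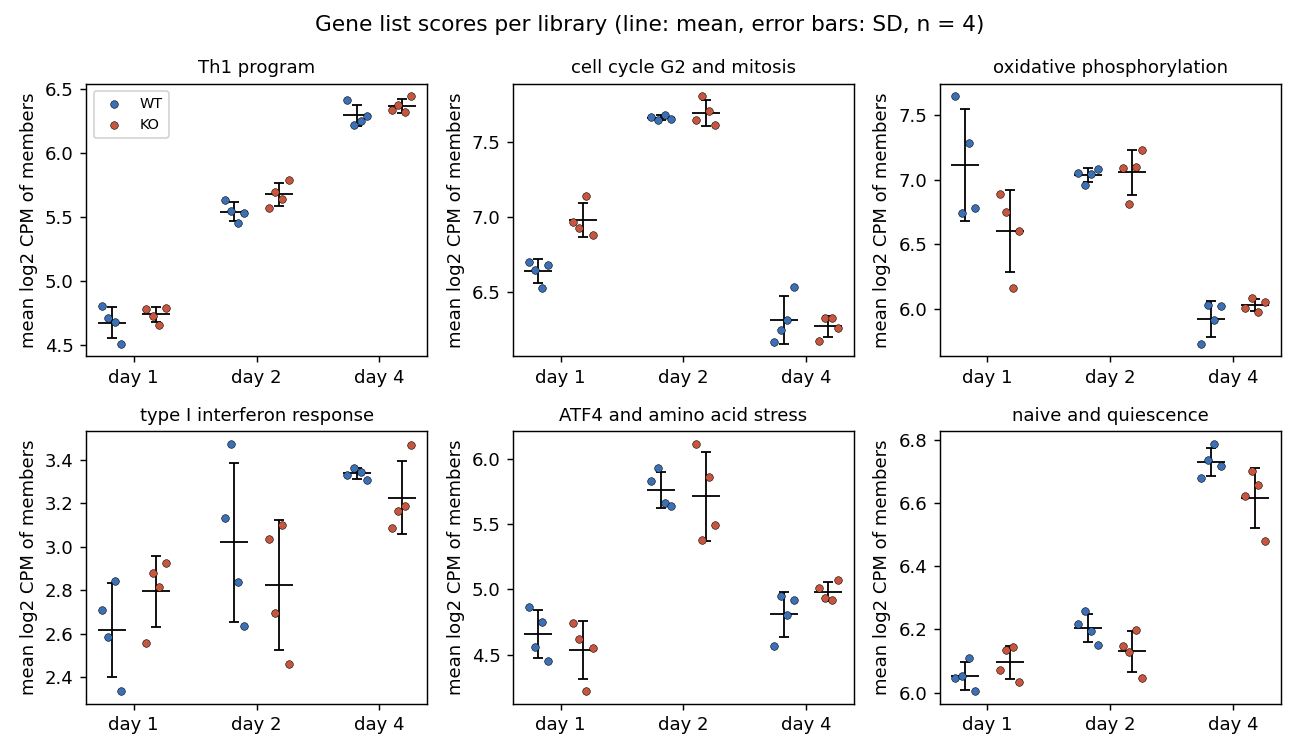
Mean log2 CPM over the members of 6 gene lists in each library by day, with a line for the mean and error bars for the SD of 4 libraries. The G2 and mitosis list is without overlap at day 1 (KO 6.88 to 7.14, WT 6.53 to 6.70), and in the other panels the KO and WT libraries of a day overlap.

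Whether the KO effect changed between days was tested with interaction terms. Rasa3 itself had a log2 difference of -0.50 between its effects at day 2 and day 1 (SE 0.228, adjusted p = 0.455, edgeR) and of 0.67 between days 4 and 2 (SE 0.225, adjusted p = 1). Il12rb2 had a difference of -1.31 between days 4 and 1 (adjusted p = 0.285) and Ifng of 1.36 (adjusted p = 0.285). No gene passed for any pair of days (0 by edgeR, DESeq2 and limma-voom). By edgeR 1605, 172 and 2530 genes had an unadjusted p under 0.05 for days 2 against 1, 4 against 2 and 4 against 1. Chance gives 754 if all days spread alike. In the oxidative phosphorylation list, 22 of 33 members had a higher KO effect at day 4 than at day 1 when adjusted over the list alone, and 8 of 20 G2 and mitosis members a lower one. The Il12rb2, Ifng and oxidative phosphorylation values rest in large part on the day 1 libraries that stood apart: without the 3 of them the difference between days 4 and 1 was -0.42 for Il12rb2 and 0.36 for Ifng (adjusted p = 1 for both).

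In WT cells the time course gave the background to these comparisons. From day 1 to day 2, 4376 of 15086 genes changed (2242 higher, 2134 lower, edgeR). Il12rb2 rose from 24.7 ± 20.6 to 243 ± 32.1 CPM (log2 change 3.29, SE 0.373, adjusted p = 1.25e-06), and the chemokine receptor gene Cxcr3 rose from 9.77 ± 3.71 to 17.3 ± 2.80 (adjusted p = 0.00137). Rasa3 fell by 0.81 on the log2 scale (adjusted p = 0.00036). Stat1 fell by 0.50 (adjusted p = 0.0236). This call was lost without the 3 day 1 libraries (log2 change -0.14, adjusted p = 0.41) or without WT day 1 replicate 1 (-0.33, 0.106). It was lost at nearly the same log2 change without WT day 1 replicate 3 (-0.44, 0.063) or WT day 2 replicate 3 (-0.45, 0.0685) or 4 (-0.47, 0.0578). The same held with the compared libraries alone (-0.51, 0.0665). Ifng stood at 101 ± 77.1 and 195 ± 34.9 CPM and did not pass (adjusted p = 0.0772), but rose with limma-voom (0.0194), without WT day 1 replicate 1 (0.00342) and without the 3 libraries (log2 change 2.13, adjusted p = 0.000905). Tbx21, Stat4 and Hck did not pass (adjusted p of 0.101, 0.0931 and 0.096), though Stat4 passed as higher without the 3 libraries (0.0302), Tbx21 as higher with the compared libraries alone (0.034) and Hck as lower without WT day 1 replicate 3 (0.0418). The largest rises were in Vldlr, a lipoprotein receptor gene (0.0639 ± 0.0538 to 11.2 ± 7.01 CPM), and in Gap43, Cwh43 and Mmp7, which had no reads at day 1 and were at least 25.1-fold, 23.4-fold and 22.0-fold higher at day 2 against a floor of 3 counts over the group. Smtnl2 and Chl1, with 2 counts and 1 count over the day 1 libraries, had ratios of 105 (95% interval 28.6 to 869) and 111 (19.5 to 4420), intervals that cover counting error only, since reads carried no molecular identifiers. The largest falls were in Apol7c (-5.18 on the log2 scale), Ifi214 (-4.85), the chemokine gene Ccl1 (-4.57), the cytokine gene Csf2 (-4.53) and the globin gene Hba-a1 (-4.37). The globin gene Hba-a2, with 2 counts over the day 2 libraries, had a ratio of 33.5 (8.93 to 282). Hba-a1, Hba-a2 and Ifi214 belong to families of near-identical genes and their values are uncertain.

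From day 1 to day 2 in WT cells, of 20 G2 and mitosis genes 18 rose and 0 fell (19 and 0 adjusted over the list alone), with the cyclin gene Ccnb1 at 92.3 ± 4.30 CPM at day 1 and 271 ± 16.8 at day 2, while of 20 S phase genes 1 rose and 9 fell (1 and 11). Of 23 glycolysis genes 18 rose (18), with the lactate transporter gene Slc16a3 at 71.4 ± 5.33 and 328 ± 43.8 CPM. Of 22 cholesterol synthesis genes 14 rose (15), and of 23 ATF4 and amino acid stress genes 15 rose (15), with 0 falling in either. Of 26 Th1 program genes 12 rose and 4 fell (16 and 5), with the transcription factor gene Hlx at 1.34 ± 0.420 and 26.2 ± 2.82 CPM and Tnf among those that fell (56.8 ± 6.68 to 9.13 ± 1.40). Of 18 cytotoxic effector genes 6 rose and 2 fell (7 and 2), with Gzmb at 58.5 ± 13.7 and 333 ± 79.0. Of 30 type I interferon response genes 9 rose and 1 fell (9 and 1), and of 25 cytokine genes 4 rose and 8 fell (7 and 9). Of 33 oxidative phosphorylation genes 1 rose and 2 fell (1 and 2). All 5 erythroid and platelet markers tested fell (5), as did 4 of 9 dendritic cell markers (5) and 3 of 10 myeloid markers (4), with 1, 0 and 0 rising in dendritic, myeloid and erythroid lists. The higher Igkc and lower Cd4 of WT day 1 replicates 1 and 3 stand beside these falls. Without the 3 day 1 libraries the count was 5430 (2761 higher, 2669 lower), and 3178 genes were shared. With upper-quartile scaling 1796 genes were higher and 2720 lower.

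From day 2 to day 4 in WT cells, 10343 genes changed (5234 higher, 5109 lower, edgeR), or 68.6% of those tested. Rasa3 rose from 13.2 ± 2.10 to 41.7 ± 3.37 CPM (log2 change 1.66, adjusted p = 1.43e-09), Il12rb2 from 243 ± 32.1 to 596 ± 60.1 (adjusted p = 0.00344) and Stat1 from 97.7 ± 8.69 to 215 ± 25.2 (adjusted p = 1.27e-06). Ifng fell by 1.03 on the log2 scale (adjusted p = 0.0264), a call lost with upper-quartile scaling (adjusted p = 0.0883), with DESeq2 (0.0669), with no filter on low counts (0.088), or without WT day 4 replicate 2 (0.0839) or WT day 2 replicate 1 (0.0565) or 4 (0.0598). Stat4, Cxcr3 and Hck did not pass (adjusted p of 0.927, 0.812 and 0.986). Tbx21, at 189 ± 16.5 and 225 ± 24.2 CPM, did not pass either (log2 change 0.26, adjusted p = 0.129), but was called as higher in 8 other fits, among them DESeq2 (0.0301), upper-quartile scaling (0.00358), a mean of at least 1 CPM (0.0409) and the compared libraries alone (0.0107). The largest rises were in genes with no reads at day 2, Odaph (at least 107-fold), the collagen gene Col4a1 (at least 82.1-fold), Gpc3 (at least 60.6-fold) and Ndst3 (at least 44.7-fold). The matrix protease gene Mmp9 rose from 0.0654 ± 0.00314 to 23.2 ± 4.74 CPM, and Col4a2, with 1 count over the day 2 libraries, had a ratio of 408 (95% interval 72.9 to 16200). Il9 had no reads at day 4 and was at least 49.0-fold lower. The cytokine gene Il22 fell by 5.29 on the log2 scale, Dnah7a by 5.01, Egr4 by 4.54 and the histone gene Hist1h2bk by 4.15, and Opn3, with 2 counts over the day 4 libraries, had a ratio of 45.9 (12.3 to 385).

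Genes of division and respiration fell together from day 2 to day 4. Of 20 S phase genes 20 fell (20 adjusted over the list alone), with Tyms at 121 ± 9.90 CPM at day 2 and 14.8 ± 2.71 at day 4, and of 20 G2 and mitosis genes 19 fell (19). Of 33 oxidative phosphorylation genes 31 fell and 1 rose (32 and 1), with Atp5b at 1956 ± 95.5 and 528 ± 48.8 CPM. Of 23 ATF4 and amino acid stress genes 16 fell and 4 rose (17 and 4), with the serine synthesis gene Psat1 at 549 ± 34.2 and 114 ± 4.15. Effector and adhesion genes rose: of 18 cytotoxic effector genes 14 rose and 2 fell (14 and 2), with perforin, Prf1, at 8.40 ± 1.61 and 135 ± 12.4 CPM. Of 26 Th1 program genes 17 rose and 4 fell (17 and 4), with Ccr5 at 138 ± 10.8 and 677 ± 111, and of 22 integrin and Rap1 adhesion genes 15 rose and 3 fell (15 and 3), with Itgb2 at 301 ± 6.92 and 811 ± 38.8. Of 20 naive and quiescence genes 13 rose and 5 fell (13 and 5), with the interleukin 7 receptor gene Il7r at 42.4 ± 16.6 and 465 ± 89.7. Of 25 cytokine genes 13 fell and 6 rose (13 and 6), of 14 inhibitory receptor genes 8 rose and 5 fell (8 and 5), and of 30 type I interferon response genes 13 rose and 5 fell (13 and 4). Of 15 B cell markers 10 rose (10) and 0 fell, with Cd22 at 5.76 ± 1.29 and 20.5 ± 7.97 CPM. With upper-quartile scaling the median of all genes was 0.27 on the log2 scale against 0.02 here (0.13 with DESeq2's factors), and 6446 genes were higher and 4030 lower, so counts of rises and falls are relative to the scaling.

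Further lists held members that changed in both directions in WT cells. From day 2 to day 4, 68.6% of all tested genes were called, so the counts below do not by themselves set a list apart. No list test was run between WT days. From day 2 to day 4, Ras and Rap regulators had 11 rises and 5 falls among 23 genes (11 and 5 adjusted over the list alone), with the Ras GTPase-activating protein gene Rasal3 at 226 ± 11.6 and 536 ± 52.2 CPM. Src family kinases and their regulators had 7 and 2 among 14 (7 and 2), T cell receptor and Ras-ERK targets 11 and 9 among 30 (11 and 9), and interferon gamma response genes 10 and 9 among 32 (10 and 8). The Th2 program had 6 rises and 6 falls among 16 (6 and 6), Th17 7 and 5 among 14 (7 and 5), the Treg signature 8 and 2 among 18 (8 and 2) and the Tfh signature 3 and 4 among 12 (3 and 4). Rorc, the Th17 transcription factor gene, rose from 7.37 ± 2.36 to 36.7 ± 9.79 CPM while Il22 of the same list fell. Glycolysis genes had 6 rises and 6 falls among 23 (6 and 6), with Ldha at 4156 ± 93.3 and 1539 ± 192 CPM, cholesterol synthesis genes 9 and 4 among 22 (9 and 4) and p53 and apoptosis genes 8 and 5 among 21 (8 and 5). Of markers of other cells, NK cell markers had 2 rises and 1 fall among 6 (2 and 1), stromal and endothelial markers 3 and 0 among 4 (3 and 0), and CD8 T cell markers 1 and 0 among 2 (1 and 0).

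**Figure D4:**
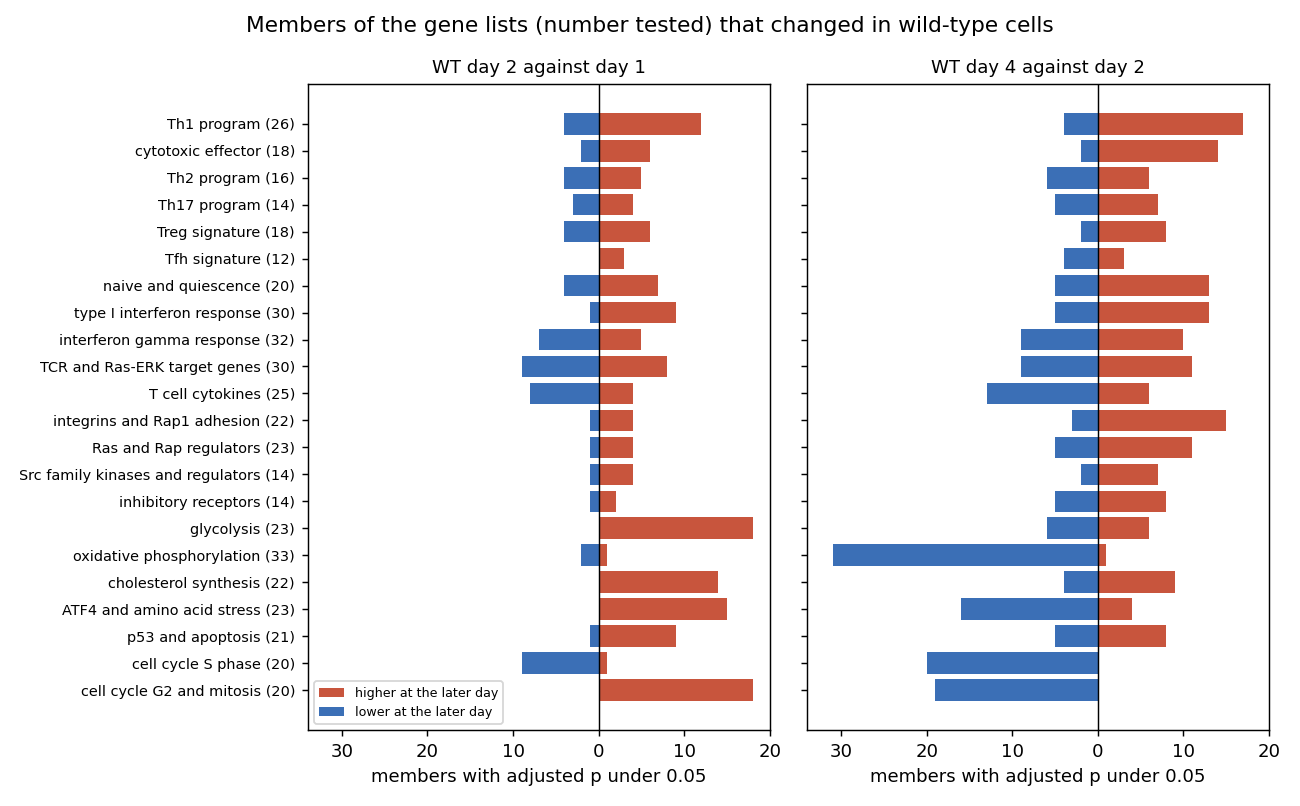
Number of members of 22 gene lists with an edgeR adjusted p under 0.05 in WT cells, higher to the right and lower to the left, from day 1 to day 2 (left) and day 2 to day 4 (right), with the number tested beside each name. G2 and mitosis genes rise at day 2 (18 of 20) and fall at day 4 (19 of 20), and oxidative phosphorylation genes fall at day 4 (31 of 33).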

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

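In this part the tests without the 3 day 1 libraries, and the use of estimated correlations to test whether members of a list vary together, were chosen after the results were seen. The fits with estimated correlations and with single libraries left out, and the tests of gene length and of other splits, were chosen before. A single library was far from the other 3 of its group in 4 of 90 combinations of group and measure, by Dixon's criterion, where chance gives about 4.5. Mitochondrial transcripts took 3.22% of counts in KO day 1 replicate 3, against 1.31% to 1.5%. Hck stood at 1.15 CPM in WT day 4 replicate 2, against 0.429 to 0.537. Ifng stood at 261 CPM in KO day 4 replicate 4, against 86.3 to 108. The number of detected genes was 19228 in KO day 2 replicate 1, against 18893 to 18906. No biological explanation was tested for these single libraries.

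The first pattern is the broad day 1 difference between KO and WT, 1606 genes by DESeq2, with oxidative phosphorylation genes lower in KO. Gene length went with the day 1 differences across genes (Spearman 0.366), yet the list's median of -0.60 lay at percentile 0 of 10000 lists matched on length and expression (random median -0.31, 95% range -0.41 to -0.20), which argues against length as the whole cause. Libraries that stand apart remain a candidate explanation, since DESeq2 called 1 gene without WT replicates 1 and 3 and KO replicate 3, and the oxidative phosphorylation list then had an adjusted p of 0.97 by camera. These fits cannot decide the question. The libraries left out were chosen after the results were seen, and fewer libraries leave fewer calls by construction. They held the highest oxidative phosphorylation scores of WT and the lowest of KO, so leaving them out shrinks the difference whatever its cause. Of 35 splits of the 8 day 1 libraries, 8 gave at least the 1 gene of the real one by edgeR, and the highest other gave 2618, which points to a structure of the samples whose source was not tested. What set these libraries apart stays open, as both WT libraries had higher Igkc and lower Cd4, but also higher Trbc1 (563 and 425 CPM, against 268 and 293) and counts on shorter genes (typical annotated gene length 3511 and 3781 bases, against 4382 and 4337).

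The second pattern is the G2 and mitosis list, higher in KO at day 1. Libraries that stand apart are argued against as its whole cause, since all 20 members were higher in KO without the 3 of them. That fit compared WT replicates 2 and 4 with KO replicates 1, 2 and 4 alone. Its adjusted p of 1.49e-21 by camera with the preset correlation takes members to vary almost independently, so it does not exclude chance. The list's median fell from 0.41 to 0.25, so part of its size went with the 3 libraries. Gene length is argued against too, since the list's median of 0.41 lay at percentile 100 of lists matched on length and expression (random median -0.09, 95% range -0.24 to 0.07). Chance and co-variation of members stay open: the list's scores did not overlap (exact permutation p = 0.0286, 0.64 after adjustment over the lists), and the list did not hold with an estimated correlation (adjusted p = 0.482). An effect of the genotype on entry into mitosis may be a biological explanation, which was not tested.

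The third pattern is the set of 11 list differences at days 2 and 4 beside at most 2 called genes. Members of a list that vary together between libraries of a group are a candidate explanation, since 1 of the 11 held with an estimated correlation. Chance could not be excluded by regrouping: 10 of 35 splits gave at least 7 lists at day 2 (highest other 13) and 24 of 35 gave at least 4 at day 4 (highest other 8). Among the 8 splits of day 4 that part all 4 pairs of numbers, as the real one does, 5 gave at least 4 lists (highest other 7), and the split of numbers 1 and 2 from 3 and 4, which is one of sex, gave 8. A genotype effect on the naive and quiescence list at day 4, the list that held, stays open as a hypothesis, and it lost its call without KO replicate 4 (adjusted p = 0.0705).

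For the counts of genes, chance could be excluded for the WT time course, where 1 of 35 splits, the real one, gave a count as large for day 2 against day 1 (4376, highest other 391) and for day 4 against day 2 (10343, highest other 0). It could not be excluded at day 2, where 2 of 35 splits gave at least the 2 genes of the real one (highest other 67). For the number of lists at day 1 it could not be excluded either, where 25 of 35 splits gave at least the 2 lists of the real one (highest other 8). Where the real count was 0 the comparison with other splits is fixed in advance and says nothing about chance: all 35 splits gave 0 at day 4. For the differences of the KO effect between days the real count of 0 was likewise met by all 100 drawn splits, whose highest counts show a structure of the samples, with 1442 for days 2 and 1, 11 for days 4 and 2, and 1275 for days 4 and 1.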

How the results depend on the processing

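Fits without the 3 day 1 libraries that stand apart, with quality weights, with days 2 and 4 alone and for the mean KO effect were chosen after seeing the data. The causes of the changes below were not tested, except that a stricter threshold or fewer genes or samples leave fewer calls by construction. Against 1 gene at day 1, DESeq2 gave 1606, quality weights 9, and limma-voom, the day's libraries alone, a threshold of 0.01 and a log2 change of at least 1 gave 0. Leaving out 1 library gave 0 (KO replicate 2, 3 or 4) to 2975 (WT replicate 2), with 2546 without WT replicate 4 and 1775 without KO replicate 1. Against 2 genes at day 2, no filter, protein-coding genes alone, limma-voom, the day's libraries alone, days 2 and 4 alone and a threshold of 0.01 each gave 1 and quality weights 9, and leaving out 1 library 1 to 2. Gm2762 was lost without WT replicate 1, 3 or 4 or KO replicate 2, 3 or 4. Against 0 genes at day 4, DESeq2, the fit without the 3 libraries, DESeq2 without them, quality weights and days 2 and 4 alone each gave 1, Rasa3 (adjusted p of 0.00305, 0.0313, 5.58e-06, 0.000254 and 0.0397). Leaving out 1 library gave 0. The differences of the KO effect stayed at 0 in all fits except quality weights, which gave 1 for days 2 and 1. The WT count of 4376 for days 2 and 1 became 7851 with quality weights, 2546 at 0.01 and 1724 with the log2 minimum (3377 to 4504 with 1 library left out), and 10343 for days 4 and 2 became 6362 with the log2 minimum (9806 to 10023). The 3 genes of the mean KO effect became 1 with limma-voom or at 0.01 and 20 with quality weights, with 3 to 5 when 1 library was left out (5 without WT day 1 replicate 2).

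For the lists, an estimated correlation gave 0, 0 and 1 at days 1, 2 and 4 and fry 1, 0 and 0, against 2, 7 and 4. Without the 3 libraries 7 passed at day 1, all higher in KO, by camera with the preset correlation alone. Oxidative phosphorylation then did not differ (adjusted p = 0.97). Its camera direction turned to higher, though its median log2 difference was -0.02 and 14 of 33 members were higher in KO. Leaving out 1 library gave 2 to 3 at day 1, 0 (KO replicate 4) to 10 (KO replicate 3) at day 2 with 4 without KO replicate 2, and 4 to 8 (WT replicate 1 or 2) at day 4.

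The labels tie no replicate numbers together, but same-numbered libraries are of the same sex in both genotypes by Xist and Y-linked transcripts, and 2, 3 and 4 of 4 KO libraries at days 1, 2 and 4 correlated best with the WT library of their number. With the replicate number as a block the counts were 1, 1 and 0 genes (Gm2762 lost, adjusted p = 0.0572), 3, 7 and 5 lists (the Th17 program gained at day 1, adjusted p = 0.0431, and B cell markers at day 4, 0.0472), and 4216 and 10296 for WT. The block changed no other call of a named gene or list. A random block within genotype gave 0, 1 and 0 genes. Across the alternatives other than single libraries left out, calls of named genes were kept 582 times, lost 31 times and gained 27 times, and calls of lists were kept 99 times, lost 28 times and turned 1 time. The gene calls include the WT day comparisons, whose genes were chosen for the largest changes. Between genotypes, other thresholds aside, Rasa3 was called in 11 of 14 fits at day 1 and 15 of 15 at day 2, and Gm2762 in 8 of 14 at day 2. Depth limits Hck, at 6 to 30 counts per library, and also Gm2762, at 6 to 12 counts per KO library and 23 to 28 per WT library at day 2.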

Other observations

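The time course of KO cells followed that of WT cells. From day 2 to day 4, 10356 genes changed in KO cells (5250 higher, 5106 lower, edgeR) and 10343 in WT cells, and the 9612 called in both all moved the same way. Log2 changes in KO and WT correlated at 0.983 (Spearman 0.984). From day 1 to day 2, 4911 genes changed in KO cells and 4376 in WT cells, with 2798 called in both, all the same way, and a correlation of 0.818 (Spearman 0.676). No gene passed the test for a difference of the KO effect between days, so the lower correlation from day 1 to day 2 is not shown to be an effect of genotype. KO effects at different days correlated across genes at 0.093 between days 1 and 2 (Spearman 0.0643), -0.196 between days 1 and 4 (Spearman -0.32) and 0.139 between days 2 and 4 (Spearman 0.0815).

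The mean KO effect over the 3 days was tested after seeing the data, and 3 genes were lower in KO. They were Rasa3 (log2 difference -1.08, SE 0.0912, adjusted p = 2.13e-07, edgeR), Gm2762 (-0.87, SE 0.14, adjusted p = 0.0104) and Ly6k (-1.30, SE 0.217, adjusted p = 0.0129), a gene of the Ly6 family of membrane proteins on chromosome 15 (ENSMUSG00000044678, 74796874 to 74799986). Ly6k and Gm2762 were named after their values were seen. With limma-voom Rasa3 alone passed. Other thresholds and single libraries left out aside, Gm2762 was called in 10 of 12 other fits (adjusted p up to 0.119, log2 differences of -0.96 to -0.85). Ly6k was called in 11 of 13 (up to 0.133, -1.32 to -0.97). Ly6k stood at 0.978 ± 0.241 CPM in KO and 3.14 ± 1.65 in WT at day 1, 0.599 ± 0.353 and 1.72 ± 0.478 at day 2, and 1.11 ± 0.299 and 1.87 ± 0.179 at day 4 (n = 4). Depth limits Ly6k too, at 10 to 22 counts per KO library at day 1, 4 to 15 at day 2 and 12 to 23 at day 4. Without the 3 day 1 libraries the log2 difference of Ly6k was -1.10 and did not pass (adjusted p = 0.133, edgeR), against -1.30 with all libraries, so the lost call does not show that those libraries made the difference. Of 100 drawn splits, 2 gave at least 3 genes, the real one included, and the highest other gave 3.

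Genes near Rasa3 can differ between strains when a targeted allele is bred into another background, and this was set as a hypothesis before the data were examined. Of 45 tested genes within 5 Mb of Rasa3, 0 passed on the mean KO effect when adjusted over the window alone, with the lowest adjusted p at Tdrp (0.147, edgeR). Windows of 2 Mb and 10 Mb held 32 and 104 genes, and 0 passed in either.

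Xist, the RNA of the inactive X chromosome, and Y-linked genes split the libraries by replicate number in both genotypes and on all 3 days, which was looked at after seeing the data. In the 12 libraries numbered 1 and 2, Xist stood at 0 to 0.979 CPM and the Y-linked Ddx3y at 61.1 to 140 CPM. In the 12 numbered 3 and 4, Xist stood at 499 to 2830 CPM and Ddx3y at up to 2.55 CPM. Numbers 1 and 2 thus carried male transcripts and numbers 3 and 4 female ones, and the split was balanced between genotypes. Between numbers 1 and 2 and numbers 3 and 4, 11 genes differed, 5 on the X and 5 on the Y chromosome, the other being Adam19 on chromosome 11 (log2 difference -0.61, adjusted p = 0.0241, edgeR). With this split as a block, 1, 2 and 0 genes and 2, 8 and 4 lists differed between KO and WT at days 1, 2 and 4.

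The Th17 program also went with the replicate number in WT cells, again seen afterwards and without a test. Its mean log2 CPM in WT numbers 1 and 2 was 3.74 and 3.96 at day 1, 3.96 and 4.20 at day 2, and 4.10 and 4.01 at day 4. In WT numbers 3 and 4 it was 3.10 and 2.99, 3.24 and 3.48, and 3.58 and 3.44. KO libraries ranged from 3.72 to 4.16. Il17f, a cytokine gene of the list, stood at 33.8, 22.8, 13.4 and 10.3 CPM in WT day 1 numbers 1 to 4 and at 32.6, 23.3, 22.7 and 40.6 in KO.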
